A study of Saccharomyces cerevisiae with 127 samples.

How the data were processed

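Per the labels, total RNA of yeast strains with a substitution in H3 or H4, grown in synthetic medium without uracil, was labelled with Cy3 and hybridised to one-colour NimbleGen expression arrays with 12 arrays per slide. The labels give 123 mutants with 1 array each, 2 arrays of H3 wild type and 2 of H4 wild type. The 12 array positions and the slide were read from the file headers, and slides are numbered 1 to 13 here. A slide held from 1 to 12 arrays.

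The deposited scanner files hold an intensity per gene on a linear scale, 1 value per gene over its probes, with 5777 genes and a median of 24 probes per gene (371 genes had fewer), per the file headers. No background column is in these files, so no background correction was made and that alternative was not run. The deposited series matrix holds natural log values for 5751 genes. The labels name variance stabilisation (VSN) and a batch correction (ComBat) for these values. The log base was taken from the values: the slope of the matrix values on the natural log of intensity, above an intensity of 500, was 0.985 as a median over arrays. The deposited ratio table holds log2 ratios of mutant to wild type for 5759 genes. For the 5751 genes also in the matrix, each ratio equalled the matrix value of the mutant minus the mean of the 2 wild types of its own histone, converted to log2, within 5.0e-08 for 123 mutants. The slide took a median of 42.6% of a gene's variance in the scanner values and 3.7% in the matrix. The 18 mitochondrially encoded genes were in the scanner files only. No depth exists for arrays, and their number limits the precision.

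Symbols came from the RefSeq gene table of the R64 assembly, where 5771 locus tags matched. No coordinates are given, since the build of the probes is not given in the sources used here. Subtelomeric genes were those within 20 kb of a chromosome end, the right end being taken from the last gene on the array. Genes with near-identical copies, such as Ty elements and the histone pairs, are uncertain because probes can read several copies. Which residue a strain carries was not checked, as an expression array does not read it.

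Scanner intensities were quantile normalised between arrays and taken as log2. Wild-type comparisons (H3 wild type against H4 wild type, all mutants, H3K56 and H4K16 substitutions against wild type) and the counts of genes per mutant used these values. Comparisons between mutants (H3 against H4, tail against core in each, H4 residues 16 to 20 and H3 residues 73 to 83 against the others) used the deposited log2 ratios. H3 tails were residues 1 to 43 and H4 tails residues 1 to 23. Each comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Standard errors are limma's.

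A set of 24 gene lists was tested with camera, with the preset correlation of 0.01 and with an estimated one, adjusted over the lists of a comparison. The lists, with the number of genes measured, were histone genes (10), silent mating loci (4 of 6), haploid-specific genes (13), a- and alpha-specific genes (11), sporulation (22), the phosphate regulon (16), galactose genes (7), amino acid biosynthesis (27 of 28), sulphur amino acid genes (21), pyrimidine biosynthesis (10), ribosomal proteins (132), ribosome biogenesis (49), stress response (30), respiration (38, or 37 in the ratios), retrograde response (9), glycolysis and ethanol (17), hexose transport (15 of 16), DNA damage response (18), G1/S genes (29), M/G1 and mitosis (22), the iron regulon (21), COS, PAU and FLO families (44), subtelomeric genes (222) and auxotrophic markers (9). The mean of each list per array was compared between groups by a two-sided permutation test with 100000 resamples, or exact where a group had fewer than 10 arrays and all groupings could be listed, and adjusted over the lists. Permutations within slides gave the within-slide p, and within-slide values are of scanner values unless named as ratios, which were added after the data were seen.

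Genes per mutant were those at least 2-fold (log2 difference of 1) from the mean of the 4 wild types. Similarity of profiles was Pearson's r over the 1000 genes of largest variance, tested one-sided by permuting residue positions. Correlations across mutants were taken after the mean of each slide was removed, over all mutants but H3V117A, which was alone on its slide, with permutation p-values adjusted over a family of 5.

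The genes named are, per comparison with a test, drawn from the 10 largest rises and 10 largest falls past the threshold (all where fewer passed), the core histone genes, and the 4 members of smallest p in each list that passed camera. Per mutant, they are drawn from the 3 largest rises and 3 largest falls among genes above the median wild-type level in the mutant or in wild type, for the 5 mutants with the largest counts and for H3K4A, H3K36A, H3K79A and H4K16A. Exceptions are named where they stand. Groups, tests, this rule and most alternatives were set before the data were examined.

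The fits were tested on simulated data with 200 changed genes. Noise was drawn independently for each gene and array from the gene's fitted spread. No slide effect and no difference between the wild types was put in, so the recoveries do not cover errors from those sources. False calls were 15 of 215 for the wild types, 13 of 120 for all mutants and 7 of 207 for H3 against H4. At a 1.5-fold and a 2-fold change, 100% and 100% of the changed genes were recovered for the wild types against each other, 27% and 80% for all mutants against wild type, 100% and 100% for H3 against H4, 93% and 98% for the H3 tail, 95% and 99% for the H4 tail, 15% and 59% for H3K56, 52% and 86% for H4K16, 66% and 95% for H4 residues 16 to 20, and 83% and 96% for H3 residues 73 to 83. Wild-type comparisons were simulated on 5777 genes and the others on 5759.

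Alternatives were median-centring, the deposited matrix, scanner values in place of ratios, slide as a block, leaving out the lowest quartile of genes by level, eBayes without a trend, other controls, other tail boundaries, each array of a small group left out in turn (for the haploid-specific means also the H4K16 substitutions together), and the replicate number as a block for the wild types. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for permutation tests and figures.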

Results

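Transcript levels were measured in budding yeast strains that each carried 1 amino-acid substitution in histone H3 or histone H4, mostly to alanine. The arrays were one-colour. Of these, 66 were H3 mutants, 57 were H4 mutants, 2 were H3 wild type and 2 were H4 wild type. Of the H3 mutants, 20 changed the N-terminal tail and 46 the histone core, and of the H4 mutants 17 changed the tail and 40 the core. Each mutant had 1 array, so values of single mutants have no replicate error. The wild-type arrays are not stated to be separate cultures, so p-values measure only the spread between these samples, which may be technical. Each array read 5777 genes, with a median of 24 probes per gene, and the median intensity of an array ranged from 227.2 to 979.6. The arrays lay on 13 slides, and slide 13 held all 4 wild-type arrays with 8 mutants. The number of arrays limits the precision of every comparison.

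The native genes for H3 (HHT1, HHT2) and H4 (HHF1, HHF2) gave low signals in wild type. Their log2 levels were 5.14 ± 0.08 for HHT1, 5.0 ± 0.04 for HHT2, 6.46 ± 0.14 for HHF1 and 6.63 ± 0.19 for HHF2 (SD, n = 4 arrays). On 7 arrays a native gene exceeded 10, against at most 9.25 on the remaining arrays. The arrays labelled H3G90A, H3T3A, H3L60A and H4S64A read HHF2 at 12.98, 12.99, 13.61 and 12.44, and HHF1 at 12.45, 11.69, 13.10 and 11.93. The array labelled H4S64A thus read native genes of the very histone its label says is changed, and that label was not checked by any other value. The arrays labelled H4I21A, H4I46A and H4G99A read HHT2 at 12.37, 11.70 and 12.62. Signal of near-identical copies is uncertain, and an expression array does not read which residue is changed.

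**Figure D1:**
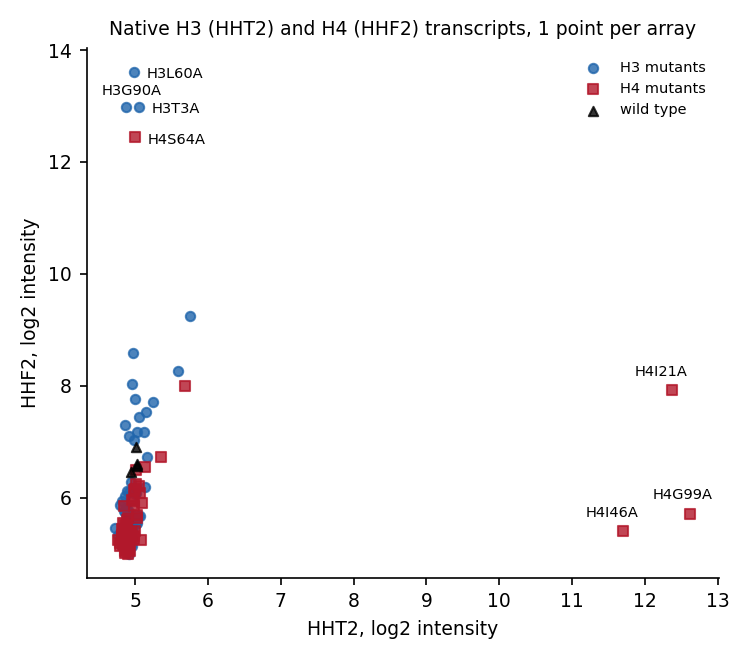
Level of HHT2 against HHF2 on each array (log2 normalised intensity on both axes, 1 point per array, wild type and mutants in separate colours). The 7 named arrays lie above 10 on either axis, and the wild-type arrays lie near 5.0 for HHT2 and 6.63 for HHF2.

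The 2 H3 wild-type arrays were set against the 2 H4 wild-type arrays to see whether they could serve as a single control. PDC5, a pyruvate decarboxylase gene named after its values were seen, was the gene at least 2-fold from the mean of the other 3 wild types on each array. Its log2 level was 8.53 and 11.63 in H3 wild type and 8.49 and 11.83 in H4 wild type. limma called 0 of 5777 genes between the wild types, and 224 genes had an unadjusted p under 0.05. Same-numbered arrays were the most alike, as for PDC5, with residual SDs of 0.073 and 0.079 against 0.099 to 0.111 for the other pairs. With the replicate number as a block limma did call genes, as given in the part on processing. The 0 thus does not show that the wild types are the same.

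What the mutants shared was tested as 123 mutant arrays against 4 wild-type arrays. The 10 largest rises, from 3.42 to 3.59 on the log2 scale, included YGR027W-A and YNL054W-A, which encode Gag proteins of Ty1 retrotransposons and have near-identical copies. YGR027W-A rose by 3.59 ± 0.59 (SE, limma adjusted p = 3.18e-06) and YNL054W-A by 3.58 ± 0.57 (limma adjusted p = 2.18e-06). Among the 10 largest falls were SET6, a SET-domain protein gene (−1.74 ± 0.33, of uncertain size because its mean of 5.78 in the mutants lay near the level of HHT2), the hexose transporter gene HXT5 (−1.72 ± 0.61), the vacuolar iron transporter gene CCC1 (−1.63 ± 0.29) and COX12, a subunit of cytochrome c oxidase (−1.55 ± 0.54). Of the 21 genes of the iron regulon, 18 rose, and 21 rose when adjusted over the list alone. They included the iron permease FTR1 (2.62 ± 0.41), the siderophore transporter SIT1 (2.34 ± 0.47) and the multicopper oxidase FET3 (1.72 ± 0.38). Of 22 genes of the M/G1 phase and mitosis, 17 rose, and 17 when adjusted over the list alone, among them ASH1, a repressor of HO in daughter cells (1.82 ± 0.30), and the cell wall glucanase SCW11 (2.53 ± 0.43). Of 29 G1/S genes, 12 rose (12 when adjusted over the list alone), among them RNR1, the large subunit of ribonucleotide reductase (3.13 ± 0.63), and POL30, the sliding clamp of DNA replication (1.98 ± 0.42). Of 38 respiration genes, 14 fell and 1 rose (18 and 1 when adjusted over the list alone), with ATP7 of the ATP synthase at −0.66 ± 0.17 and QCR8 of the cytochrome bc1 complex at −1.35 ± 0.36. Of 30 stress genes 3 fell and 1 rose, 0 when adjusted over the list alone, and the disaggregase HSP104 was at −0.57 ± 0.21 (SE, limma adjusted p = 0.042).

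limma called 1213 of 5777 genes between all mutants and wild type, 601 higher and 612 lower in the mutants. By camera, adjusted over the 24 lists, the iron regulon had a median log2 difference of 1.54 (adjusted p = 5.09e-15) and the M/G1 list one of 1.32 (adjusted p = 7.82e-12). Both had adjusted p = 0.208 with an estimated correlation. The G1/S list had a median of 0.54 (adjusted p = 1.18e-06; adjusted p = 0.763 with an estimated correlation), and respiration one of −0.50 (adjusted p = 3.53e-05; adjusted p = 0.846 with an estimated correlation). The stress list had a median of −0.42 (adjusted p = 0.00643; adjusted p = 0.965 with an estimated correlation). Two-sided permutation tests of list means shuffled arrays over all slides, so they do not separate mutant from slide. In them the iron regulon was 1.51 higher in the mutants (permutation test, adjusted p = 0.00036, lower in 6 of 123 mutants). Its means were 10.86 ± 0.65 (SD, n = 123) in mutants and 9.35 ± 0.08 (SD, n = 4) in wild type. The M/G1 mean was 1.20 higher (permutation test, adjusted p = 0.00036, in all but 3 mutants), the G1/S mean 0.71 higher (adjusted p = 0.026, all but 2) and the respiration mean lower at −0.49 (adjusted p = 0.045, all but 6). limma called 0 genes with slide as a block (75 at an unadjusted p under 0.05). Within slide 13 alone, 8 mutants against 4 wild types, it also called 0 genes, with 519 at an unadjusted p under 0.05. With that block YGR027W-A was at 0.27, YNL054W-A at 0.35, SET6 at −0.28, HXT5 at −0.75, CCC1 at −0.19, COX12 at −0.55, FTR1 at 0.55, SIT1 at −0.09 and FET3 at −0.01. ASH1 was at 0.85, SCW11 at 0.65, RNR1 at 0.65, POL30 at 0.45, ATP7 at −0.22, QCR8 at −0.24 and HSP104 at −0.21. Within slide 13 the list means differed by 0.06 for the iron regulon, 0.27 for M/G1, 0.25 for G1/S, −0.12 for respiration and −0.23 for stress. Leaving out H3 wild type 1 or 2, or H4 wild type 1 or 2, gave 628, 630, 568 and 524 genes by limma, and the deposited matrix gave 0 (418 at an unadjusted p under 0.05).

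The 66 H3 mutants were set against the 57 H4 mutants in the deposited log2 ratios to wild type. These ratios carry the difference between the H3 and H4 wild types, so the standard errors leave out the spread of the wild-type arrays. In the deposited matrix, without that difference, limma called no gene. Every measured gene of the silent mating loci was higher in H3 mutants, 4 of 4 over all genes and 4 when adjusted over the list alone, among them HMRA1 (0.32 ± 0.09, SE). Of 7 galactose genes 4 rose (4 when adjusted over the list alone), with GAL10, the epimerase, at 0.37 ± 0.05 and the galactose permease GAL2 at 0.30 ± 0.05. The largest rises included the phosphate transporter PHO89 (0.72 ± 0.11), GPD2, a glycerol-3-phosphate dehydrogenase (0.71 ± 0.14), and the mitochondrial co-chaperone MDJ2 (0.68 ± 0.10). The largest falls included the septin CDC12 (−0.59 ± 0.08), the methionine salvage enzyme MRI1 (−0.59 ± 0.10) and the corepressor TUP1 (−0.57 ± 0.08; limma adjusted p = 1.60e-09). Of 132 ribosomal protein genes 30 rose and 1 fell (29 and 1 when adjusted over the list alone), with RPL15B at 0.20 ± 0.04. Of 22 sporulation genes 9 rose (9 when adjusted over the list alone), with the meiotic regulator NDT80 at 0.32 ± 0.04. Of 15 hexose transport genes 8 rose (8 when adjusted over the list alone), with HXT8 at 0.25 ± 0.05. Of 30 stress genes 8 rose (7 when adjusted over the list alone), with the small heat shock protein HSP26 at 0.33 ± 0.07. Of 21 iron genes 10 fell and 1 rose, the same numbers when adjusted over the list alone, with the copper pump CCC2 at −0.38 ± 0.07.

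limma called 1977 of 5759 genes between H3 and H4 mutants, 913 higher and 1064 lower in H3 mutants. By camera the ribosomal proteins had a median difference of 0.09 (adjusted p = 5.34e-06), sporulation 0.08 and hexose transport 0.16 (adjusted p = 0.017 for both), silent mating loci 0.21 and iron −0.15 (adjusted p = 0.034 for both), and galactose 0.16 and stress 0.07 (adjusted p = 0.046 for both). All 7 had adjusted p = 0.902 with an estimated correlation. In two-sided permutation tests of list means, the silent mating loci were 0.23 higher (adjusted p = 0.0012, 49 of 66 H3 mutants) and the galactose genes 0.12 higher (adjusted p = 0.0014, 52 of 66). Within slides these means differed by 0.13 and 0.14 in the ratios (permutation test, adjusted p = 0.63 and 0.12) and by −0.02 and 0.04 in the scanner values. Slides 2 and 8 each held a single H3 mutant, H3L100A and H3S10A, so their values are those of 1 array. On slides 2, 8, 12 and 13 in turn the silent mating loci differed by 0.34, 0.40, 0.01 and 0.05 in the ratios and 0.09, 0.09, −0.02 and −0.11 in the scanner values. The galactose genes differed by 0.13, 0.24, 0.18 and 0.04 in the ratios and 0.01, 0.23, 0.05 and −0.05 in the scanner values. The haploid-specific mean, 0.09 higher over all arrays (permutation test, adjusted p = 0.52), was 0.54 higher within slides in the ratios (adjusted p = 0.03) and 0.47 in the scanner values (adjusted p = 0.11). Its ratios differed by 0.47, 0.36, 0.29 and 1.0 on the 4 slides, with H4K16R and H4K16Q among the 3 H4 mutants of slide 13. In the scanner values of the same slides ribosomal proteins differed by −0.06, −0.21, 0.02 and −0.12, sporulation by 0.13, −0.14, −0.04 and −0.06, and hexose transport by 0.05, 0.03, −0.01 and 0.07. The iron regulon differed there by −0.02, −1.15 (H3S10A alone), −0.08 and 0.20, and stress by 0.42, 0.47, −0.26 and −0.13. In the scanner values with slide as a block the median turned to −0.05 for ribosomal proteins (camera adjusted p = 1.84e-04; adjusted p = 0.916 with an estimated correlation) and −0.02 for sporulation. Without the block it was −0.04 for both ribosomal proteins and stress. In the deposited matrix it was −0.03 for both. Each ratio was formed against the wild type of its own histone, so the difference between those wild types enters every value with its sign turned. For genes in both, the ratio and matrix comparisons differ only by this difference, taken from 2 arrays of each wild type. limma on the ratios leaves out the spread of those arrays. It called 0 genes in the matrix, so the 1977 calls rest on the wild-type difference. In the deposited matrix the median of H3 minus H4 wild type was −0.206 for the silent mating loci, −0.125 for ribosomal proteins, −0.105 for sporulation, −0.167 for hexose transport, −0.101 for galactose, −0.073 for stress and 0.067 for iron. With the sign turned, these were about as large as the medians between the mutants for silent mating loci, ribosomal proteins, sporulation, hexose transport and stress, and smaller for galactose and iron. In the scanner values limma called 0 genes with slide as a block (94 at an unadjusted p under 0.05), and the deposited matrix also gave 0 by limma (70). Scanner values with that block gave 0.08 for PHO89, 0.71 for GPD2, 0.24 for MDJ2, −0.06 for CDC12, −0.18 for MRI1, −0.07 for TUP1, 0.05 for GAL10, 0.11 for GAL2, −0.02 for NDT80, −0.11 for HMRA1, 0.01 for RPL15B, 0.04 for HSP26, 0.05 for HXT8 and −0.13 for CCC2. The deposited ratios with that block gave 174 genes, and in the scanner values within slides 2, 8, 12 and 13 limma called 0 genes each, with 8, 291, 978 and 177 at an unadjusted p under 0.05.

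H3 tail mutants (20) were set against H3 core mutants (46), which asks whether the unstructured tail and the folded core differ in effect. The 22 sporulation genes had a lower median in tail mutants (−0.10), with SPO13, a regulator of meiosis I, at −0.19 ± 0.10 and the meiotic recombinase DMC1 at −0.15 ± 0.09 (SE). The subtelomeric COS, PAU and FLO families had a median of −0.09, with COS12 at −0.38 ± 0.23, and the 222 subtelomeric genes one of −0.04, with the aryl-alcohol dehydrogenase AAD4 at −0.24 ± 0.13. The 13 haploid-specific genes had a median of 0.10 and the 11 a- and alpha-specific genes one of 0.16. By camera the adjusted p was 7.11e-07 for sporulation (adjusted p = 0.311 with an estimated correlation). For the COS, PAU and FLO families it was 9.93e-06, for subtelomeric genes 4.16e-04 and for haploid-specific genes 4.79e-04 (adjusted p = 0.443 with an estimated correlation for all 3). For a- and alpha-specific genes it was 0.035 (adjusted p = 0.620 with an estimated correlation). Amino acid biosynthesis had a median of 0.05 (adjusted p = 3.90e-04) and galactose genes one of −0.05 (adjusted p = 0.040), both with adjusted p = 0.443 with an estimated correlation. Pyrimidine biosynthesis at −0.07 (adjusted p = 0.010), the phosphate regulon at −0.07 (adjusted p = 0.027) and the DNA damage response at −0.03 (adjusted p = 0.035) had adjusted p = 0.373 with an estimated correlation. Ribosomal proteins at −0.02 (adjusted p = 0.022) and respiration at −0.03 (adjusted p = 0.035) had a median of 0.04 each in the scanner values. Both, and the sulphur amino acid genes at 0.07 (adjusted p = 0.048), had adjusted p = 0.826 with an estimated correlation. limma called 0 genes, with 16 of 5759 at an unadjusted p under 0.05, and 0 in each of the 13 lists when adjusted over the list alone. Slide 10 held 11 of the 20 tail mutants and no core mutant. In the batch-corrected matrix behind the ratios the slide took a median of 3.7% of a gene's variance. A tail-core difference that lay between slides may have been removed with it. The 0 thus does not show that tail and core are alike in effect. With slide as a block in the scanner values SPO13 was at −0.43, DMC1 at −0.33, COS12 at −0.99 and AAD4 at −0.82, and limma again called 0 genes. Within slides 4 and 13, limma called in the scanner values 0 genes (71 and 204 at an unadjusted p under 0.05). In these values the sporulation mean differed by −0.15 and −0.21 there, the COS, PAU and FLO mean by −0.39 and −0.06, the subtelomeric mean by −0.19 and 0.05 and the haploid-specific mean by 0.15 and 0.27. Scanner values without the block gave 280 genes by limma, 139 higher and 141 lower.

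H4 tail mutants (17) were set against H4 core mutants (40). STE12, the transcription factor of the mating response, fell (−0.57 ± 0.14, SE), as did FAR1, the pheromone-induced inhibitor of the G1 cyclins (−0.88 ± 0.24), the cell wall protein gene GAS3 (−0.63 ± 0.16) and PMU1 (−0.55 ± 0.14). Rises were seen for the carnitine acetyltransferase YAT1 (0.98 ± 0.25), the glycerol-3-phosphate dehydrogenase GPD2 (0.87 ± 0.23), the aquaporin AQY1 (0.76 ± 0.19), the kinase RCK1 (0.60 ± 0.14) and QCR6 of the cytochrome bc1 complex (0.37 ± 0.09). The limma adjusted p was 0.048 for FAR1 and GPD2 and 0.045 for the others. Of the haploid-specific genes 1 of 13 fell (6 when adjusted over the list alone). Of the a- and alpha-specific genes 0 of 11 passed (6 fell when adjusted over the list alone), with the receptor gene STE3 at −0.47 ± 0.14 and the pheromone gene MF(ALPHA)1 at −1.05 ± 0.33. Of the G1/S genes 0 of 29 passed (8 fell when adjusted over the list alone; the cyclin CLN2 was at −0.46 ± 0.15), and of the M/G1 genes 0 of 22 (8 fell and 1 rose when adjusted over the list alone; the regulator SWI5 was at −0.47 ± 0.17). Of the respiration genes 1 of 37 rose (3 when adjusted over the list alone), of amino acid biosynthesis 0 of 27 (4 when adjusted over the list alone; LYS20 of lysine synthesis was at 0.37 ± 0.10), of stress genes 0 of 30 (0 when adjusted over the list alone; TSL1 of trehalose synthesis was at 0.30 ± 0.11), and of glycolysis and ethanol genes 0 of 17 (3 fell when adjusted over the list alone; TDH2, a glyceraldehyde-3-phosphate dehydrogenase, was at −0.34 ± 0.11).

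limma called 54 of 5759 genes between H4 tail and core mutants, 16 higher and 38 lower in tail mutants. By camera the G1/S list (median −0.19) had adjusted p = 2.30e-05, stress (0.19) 2.7e-05, respiration (0.11) 1.21e-04, and the haploid-specific (−0.32) and a- and alpha-specific genes (−0.37) 5.78e-04. Amino acid biosynthesis (0.11) and M/G1 (−0.20) had adjusted p = 0.00201. All 7 had adjusted p = 0.650 with an estimated correlation. Glycolysis and ethanol (−0.08) had adjusted p = 0.023 (adjusted p = 0.776 with an estimated correlation). The haploid-specific mean ratio was −0.64 ± 0.73 in tail mutants (SD, n = 17) and −0.25 ± 0.49 in core mutants (SD, n = 40). The difference of −0.39 did not pass a two-sided permutation test (p = 0.020, adjusted p = 0.11, lower in 11 of 17), and within slides it was −0.66 in the ratios (permutation p = 0.028, adjusted p = 0.13) and −0.65 in the scanner values (permutation p = 0.053, adjusted p = 0.21). It was −0.28 without H4K16Q (−2.33), −0.30 without H4H18A (−2.05), −0.32 without H4K16A (−1.79) and −0.17 without the 3 H4K16 substitutions, a setting chosen after the data were seen (permutation p = 0.29). On slides 6, 8, 12 and 13 the haploid-specific mean ratio differed by −0.65, −0.28, −0.35 and −1.59. In the scanner values it differed there by −0.75, −0.24, −0.10 and −1.56, the a- and alpha-specific mean by −1.04, −0.41, −0.44 and −1.85, the G1/S mean by −0.08, −0.42, −0.21 and 0.05 and the stress mean by 0.23, 0.46, 0.10 and −0.12. With slide as a block in the scanner values limma called 311 genes, 31 of them among the 54, and the ratios with that block gave 743, including all 54. In the scanner values with the block YAT1 was at 1.84, GPD2 at 2.28, AQY1 at 1.36, RCK1 at 1.09, QCR6 at 0.60, PMU1 at −0.91 and STE12 at −0.85, all with limma adjusted p under 0.05. FAR1 at −1.41 had limma adjusted p = 0.067, and GAS3 at −0.71 had limma adjusted p = 0.137. Within slides 6, 8, 12 and 13 limma called, in the scanner values, 0 (570 at an unadjusted p under 0.05), 9, 2190 and 2 genes, with a single core mutant on slides 12 and 13 and a single tail mutant on slide 8. On slide 13 that core mutant was the array labelled H4S64A, with native H4 signal (HHF1 11.93, HHF2 12.44). The call ended, with 0 genes by limma, when the lowest quartile of genes by level was left out (933 at an unadjusted p under 0.05) or when the tail was taken to residue 29 (414). Without the 7 arrays with native histone signal 1 gene was called. Whether tail and core differed otherwise in H4 than in H3 was tested as an interaction, where limma called 0 genes (457 at an unadjusted p under 0.05). For the haploid-specific genes the interaction was 0.51 (two-sided permutation p = 0.012, adjusted p = 0.21).

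H3 lysine 56, a core residue that is acetylated on new histones, was changed to alanine, arginine and glutamine, and these 3 arrays were set against the 4 wild types. The fit treats the 3 arrays as replicates of a changed residue. They are different genotypes, so the standard errors mix differences between substitutions with technical spread. Ribosomal protein genes had a median of 0.30, with RPL15A at 0.48 ± 0.09 and RPL43B at 0.45 ± 0.10 (SE), and the ribosome biogenesis genes one of 0.27, with the snoRNP protein gene GAR1 at 1.07 ± 0.33. G1/S genes had a median of 0.71, with POL30 at 2.22 ± 0.63 and the S-phase cyclin CLB5 at 1.34 ± 0.47, and M/G1 genes one of 1.04. Stress genes had a median of −0.45, with phosphoglucomutase PGM2 at −0.78 ± 0.15 and catalase CTT1 at −1.49 ± 0.53. Respiration genes had a median of −0.26, with the dehydrogenase subunits KGD1 (−0.62 ± 0.12) and SDH1 (−0.60 ± 0.12) and ATP2 of the ATP synthase (−0.53 ± 0.11). Sulphur amino acid genes had a median of −0.96, with the ATP sulphurylase MET3 at −0.84 ± 0.27 and the sulphate permease SUL2 at −1.94 ± 0.66. By camera the adjusted p was 1.23e-17 for ribosomal proteins, 8.35e-07 for G1/S, 2.36e-05 for M/G1, 1.95e-04 for respiration and 2.22e-04 for sulphur amino acid genes, each with adjusted p = 0.599 with an estimated correlation. It was 1.72e-05 for stress and 6.97e-05 for ribosome biogenesis (adjusted p = 0.600 with an estimated correlation). Pyrimidine biosynthesis had a median of 0.44 (adjusted p = 0.00588; adjusted p = 0.599 with an estimated correlation). The iron regulon at 0.37 (adjusted p = 0.00588), which was at −0.03 with slide as a block, and amino acid biosynthesis at −0.47 (adjusted p = 0.00803) had adjusted p = 0.621 with an estimated correlation.

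For H3K56, limma called 0 of 5777 genes, with 1159 at an unadjusted p under 0.05, and 0 members of these lists over all genes. When adjusted over the list alone, 1 stress gene and 3 respiration genes fell, 1 M/G1 gene rose and 0 genes passed in the other lists. The list means of ribosomal proteins (0.31), sulphur amino acid genes (−0.94) and stress (−0.55) each moved the same way in 3 of 3 substitutions. Each had two-sided exact permutation p = 0.029, the smallest that 3 against 4 arrays allow (adjusted p = 0.076). Only the arginine and glutamine arrays shared slide 13 with the wild types, and there the means differed by 0.20, −0.43 and −0.16 (exact permutation p = 0.067, the smallest possible, adjusted p = 0.16). The G1/S mean was 9.19 in H3K56A, 8.25 in H3K56R and 7.48 in H3K56Q against 7.41 to 7.51 in the wild types, and the M/G1 mean 9.89, 9.55 and 8.31 against 8.31 to 8.42, so the glutamine array stood at the wild-type level for both. G1/S differed on slide 13 by 0.40, M/G1 by 0.57, respiration by −0.15, ribosome biogenesis by 0.12, pyrimidine biosynthesis by 0.17, amino acid biosynthesis by −0.08 and iron by 0.05. limma with slide as a block called 331 genes, 162 higher and 169 lower, with RPL15A at 0.46, RPL43B at 0.37, PGM2 at −0.69, KGD1 at −0.59, SDH1 at −0.49, ATP2 at −0.47 and CLB5 at 0.71 past the threshold. CTT1 at −0.84, POL30 at 1.53, MET3 at −0.66, SUL2 at −1.14 and GAR1 at 0.66 were not. Within slide 13 limma called 347 genes. Leaving out H3K56A gave 347 genes and leaving out H3K56Q gave 825, while the deposited matrix gave 472.

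H4 lysine 16, a tail residue that can be acetylated and lies in the patch bound by the silencing protein Sir3, was likewise changed to alanine, arginine and glutamine. As for H3K56, the fit treats 3 different genotypes as replicates of a changed residue. All 3 arrays had lower levels of genes of the mating response than all 4 wild types. The falls on the log2 scale were −2.68 ± 0.31 (SE) for SST2, a regulator of pheromone desensitisation, −2.24 ± 0.27 for FAR1 (5.77 in H4K16A and 5.22 in H4K16Q, near the level of HHT2, so its size is uncertain), −1.88 ± 0.22 for the pheromone gene MF(ALPHA)1 and −1.65 ± 0.20 for the transcription factor gene TEC1. The a-factor exporter STE6 was at −1.47 ± 0.16, the cell fusion gene FUS1 at −1.38 ± 0.15, the karyogamy regulator KAR4 at −1.17 ± 0.11 and YPL257W at −0.70 ± 0.09. The transporter gene ATR1 rose by 0.83 ± 0.10 and MET5, a sulphite reductase subunit, by 0.60 ± 0.07. These were all 10 genes that passed, each at limma adjusted p = 0.047. Of the 13 haploid-specific genes 3 fell over all genes and 13 when adjusted over the list alone, and of the 11 a- and alpha-specific genes 2 fell (9 when adjusted over the list alone). The agglutinin subunit AGA1 was at −2.69 ± 0.47, the pheromone protease BAR1 at −4.02 ± 0.67 and ASG7 at −2.98 ± 0.45 (SE). Of 49 ribosome biogenesis genes 0 passed over all genes and 21 rose when adjusted over the list alone, with NOP1 of the snoRNPs at 0.80 ± 0.18 and RRP12 at 0.57 ± 0.11. Of 27 amino acid genes 0 passed over all genes, and 8 rose and 1 fell when adjusted over the list alone, with TRP3 at 0.48 ± 0.10, ASN1 at 0.67 ± 0.14 and HIS3 at −2.45 ± 0.47. Of 21 sulphur amino acid genes 1 rose (1 when adjusted over the list alone). Of 30 stress genes 0 passed (3 fell when adjusted over the list alone), with PGM2 at −0.36 ± 0.07.

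**Figure D2:**
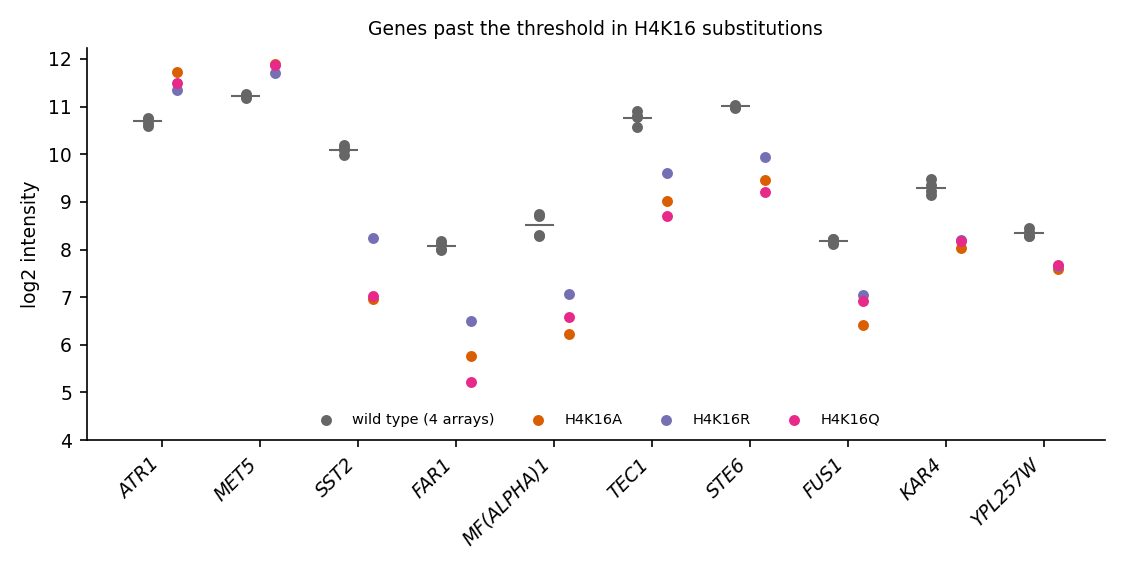
Level (log2 normalised intensity) of the 10 genes past the threshold in the H4K16 comparison, for the 4 wild-type arrays (grey) and H4K16A, H4K16R and H4K16Q. The line is the wild-type mean; 8 genes lie below it and 2 above it in all 3 substitutions.

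By camera the H4K16 comparison gave adjusted p = 3.41e-11 for the haploid-specific genes (median −1.81), 1.72e-10 for ribosome biogenesis (0.32) and 5.86e-10 for the a- and alpha-specific genes (−2.49), all with adjusted p = 0.375 with an estimated correlation. Ribosomal proteins (0.16, with RPL5 at 0.52 ± 0.10, SE) had adjusted p = 1.22e-08 (adjusted p = 0.633 with an estimated correlation) and stress (−0.24) 4.26e-06 (adjusted p = 0.47 with an estimated correlation). Amino acid biosynthesis (0.22) had adjusted p = 1.28e-05 (adjusted p = 0.0887 with an estimated correlation). Sulphur amino acid genes (0.36) and respiration (−0.28) had adjusted p = 3.88e-05 each (adjusted p = 0.513 and adjusted p = 0.521 with an estimated correlation). M/G1 (0.32) had adjusted p = 0.010 (adjusted p = 0.654 with an estimated correlation), glycolysis and ethanol (−0.11) 0.011 (adjusted p = 0.521 with an estimated correlation) and pyrimidine biosynthesis (0.17) 0.020 (adjusted p = 0.375 with an estimated correlation). The iron regulon (0.50, adjusted p = 0.011; adjusted p = 0.746 with an estimated correlation) turned to −0.23 in the deposited matrix and −0.14 with slide as a block. In ribosomal proteins, respiration, M/G1, iron, glycolysis and pyrimidine lists 0 genes passed over all genes or when adjusted over the list alone. The haploid-specific mean was 7.83 ± 0.78 (SD, n = 3) against 9.55 ± 0.01 (SD, n = 4) in wild type. The difference of −1.72 had a two-sided exact permutation p = 0.029, the smallest possible (adjusted p = 0.076, lower in 3 of 3), and the mean was 7.63 in H4K16A, 8.70 in H4K16R and 7.17 in H4K16Q. Within slide 13, where the arginine and glutamine arrays lay, it was −1.61 (exact permutation p = 0.067, the smallest possible, adjusted p = 0.20), and the a- and alpha-specific mean was −1.84. Ribosome biogenesis differed there by 0.33, ribosomal proteins by 0.24, stress by −0.18, amino acid biosynthesis by 0.13, sulphur amino acid genes by 0.18, respiration by −0.10, glycolysis and ethanol by −0.19, pyrimidine biosynthesis by 0.14, iron by −0.15 and M/G1 by 0.11. The M/G1 mean was 9.60 in H4K16A, 8.64 in H4K16R and 8.30 in H4K16Q against 8.31 to 8.42 in wild type, and the iron mean 11.39, 9.26 and 9.14 against 9.27 to 9.43.

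limma called 10 of 5777 genes for H4K16, 2 higher and 8 lower, with 1188 at an unadjusted p under 0.05. Blocking on slide it called 636, 374 higher and 262 lower, including all 10. There SST2 was at −2.45, FAR1 at −2.21, MF(ALPHA)1 at −1.68, TEC1 at −1.61, STE6 at −1.43, FUS1 at −1.19, KAR4 at −1.12, YPL257W at −0.68, ATR1 at 0.73 and MET5 at 0.57. AGA1 at −3.07, BAR1 at −3.56, ASG7 at −2.62, HIS3 at −1.99, ASN1 at 0.51, NOP1 at 0.66, RRP12 at 0.53, RPL5 at 0.50 and PGM2 at −0.36 passed with that block. Within slide 13 limma called 639 genes, 378 higher and 261 lower. Leaving out H3 wild type 1 or 2, or H4 wild type 1 or 2, ended the call with 0 genes by limma (743, 710, 729 and 634 at an unadjusted p under 0.05). Leaving out H4K16Q gave 1 gene, H4K16R 136 and H4K16A 639, the last both including all 10. Median-centring gave 3 genes, 0 higher and 3 lower. Leaving out the lowest quartile of genes by level gave 1 gene, the deposited matrix 476, and H4 wild type alone as control 0 by limma (284 at an unadjusted p under 0.05).

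H4 residues 16 to 20 form the basic patch of the tail, and its 5 alanine mutants were set against the other 50 H4 mutants without the remaining H4K16 substitutions. The haploid-specific genes had a median of −0.62, with the scaffold STE5 at −0.47 ± 0.17, the protease AXL1 at −0.61 ± 0.22 and FAR1 at −0.95 ± 0.37 (SE). The a- and alpha-specific genes had a median of −0.69, with the receptor STE2 at −0.93 ± 0.39 and BAR1 at −0.98 ± 0.46. Amino acid biosynthesis genes had a median of 0.21, with ILV6 of branched-chain synthesis at 0.28 ± 0.09 and LYS1 of lysine synthesis at 0.48 ± 0.18. limma called 0 of 5759 genes (242 at an unadjusted p under 0.05), and 10 haploid-specific genes passed when adjusted over the list alone, against 0 in the other lists. By camera the adjusted p was 2.79e-13 for the haploid-specific genes (adjusted p = 0.167 with an estimated correlation), and 1.04e-07 for amino acid biosynthesis and 2.54e-06 for the a- and alpha-specific genes (adjusted p = 0.418 with an estimated correlation for both). Ribosomal proteins (0.12, adjusted p = 1.82e-08), subtelomeric genes (0.11, adjusted p = 4.53e-05), the COS, PAU and FLO families (0.23, adjusted p = 9.44e-05), ribosome biogenesis (0.12, adjusted p = 2.07e-04), sulphur amino acid genes (0.25, adjusted p = 9.62e-04) and iron (0.12, adjusted p = 0.00843) each had adjusted p = 0.824 with an estimated correlation. The haploid-specific mean ratio was −0.89 ± 0.98 (SD, n = 5) against −0.27 ± 0.45 (SD, n = 50), a difference of −0.62 (two-sided permutation test, p = 0.016, adjusted p = 0.39, lower in 3 of 5). The single values were −1.79 in H4K16A, −2.05 in H4H18A, −0.58 in H4R19A, −0.08 in H4R17A and 0.08 in H4K20A. The difference was −0.33 without H4H18A (permutation p = 0.18) and −0.39 without H4K16A (permutation p = 0.11), settings chosen after the data were seen. All 5 lay on slide 6, where the mean ratio differed by −0.87 (permutation p = 0.032, adjusted p = 0.58). In the scanner values of slide 6 the haploid-specific mean differed by −1.06 (permutation p = 0.028, adjusted p = 0.37), the a- and alpha-specific mean by −1.22, and amino acid biosynthesis by 0.13. In these values limma called 0 genes within slide 6 (353 at an unadjusted p under 0.05). Blocking on slide gave 0 genes by limma, with STE5 at −0.72, AXL1 at −1.10, FAR1 at −1.59, STE2 at −2.04, BAR1 at −2.02, ILV6 at 0.38 and LYS1 at 0.47 in the scanner values. Scanner values without that block gave 4 genes, and the wild types as control 2537. The wild types lay on another slide than these 5 mutants, so the 2537 genes cannot be told apart from a slide difference.

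H3 residues 73 to 83 hold the loop around lysine 79, a methylated residue tied to silencing, and these 9 mutants were set against the other 57 H3 mutants. The haploid-specific genes had a median of −0.36, with FAR1 at −0.71 ± 0.27, the G-protein subunit GPA1 at −0.43 ± 0.17 and the endonuclease HO at −0.48 ± 0.19 (SE). FUS1 was at −0.63 ± 0.27, and in the a- and alpha-specific list, with a median of −0.27, BAR1 was at −0.70 ± 0.32 and STE2 at −0.51 ± 0.25. The iron regulon had a median of 0.24, with CCC2 at 0.36 ± 0.13 and the reductase FRE5 at 0.80 ± 0.32. The G1/S list had a median of −0.13, with the cyclin CLN1 at −0.39 ± 0.22. limma called 0 of 5759 genes (297 at an unadjusted p under 0.05) and 0 in these lists when adjusted over the list alone. By camera the adjusted p was 3.63e-08 for both the haploid-specific and the iron list (adjusted p = 0.213 and adjusted p = 0.682 with an estimated correlation). It was 8.57e-04 for G1/S (adjusted p = 0.780 with an estimated correlation), 0.00247 for the a- and alpha-specific genes and 0.017 for the auxotrophic markers with a median of −0.12 (adjusted p = 0.723 with an estimated correlation for both). Ribosomal proteins (−0.08, adjusted p = 1.13e-05) and M/G1 (−0.18, adjusted p = 0.030) had adjusted p = 0.780 with an estimated correlation, and their medians were 0.05 and 0.03 in the scanner values. The haploid-specific mean ratio was −0.62 ± 0.58 (SD, n = 9) against −0.23 ± 0.36 (SD, n = 57), a difference of −0.39 (two-sided permutation test, p = 0.0088, adjusted p = 0.21, lower in 7 of 9). Within slides 3 and 11 it differed by −0.55 and −0.45 in the ratios (pooled −0.50, permutation p = 0.0070, adjusted p = 0.17) and by −0.32 and −0.43 in the scanner values (pooled −0.37, permutation p = 0.031, adjusted p = 0.34). H3E73A (−1.97) carried much of it: without that array, a setting chosen after the data were seen, the difference was −0.22 (permutation p = 0.10, adjusted p = 0.61), with 0.02 within slide 11 in the scanner values and −0.31 within slides in the ratios (permutation p = 0.031). With H3E73A, in the scanner values of slides 3 and 11, the a- and alpha-specific mean differed by −0.21 and −0.35, the iron mean by 0.09 and 0.22 and the G1/S mean by 0.04 and −0.36. Within these slides limma called 0 genes (162 and 751 at an unadjusted p under 0.05). With slide as a block limma called 0 genes, with FAR1 at −0.71, GPA1 at −0.39, HO at −0.49, FUS1 at −0.57, BAR1 at −0.58, STE2 at −0.49, CCC2 at 0.26, FRE5 at 0.53 and CLN1 at −0.40 in the scanner values. With the wild types as control limma called 3645 genes, and FAR1, HO, BAR1 and CLN1 turned to 0.27, 0.52, 0.03 and 0.43. The wild types lay on another slide than these 9 mutants, so these values cannot be told apart from a slide difference.

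**Figure D3:**
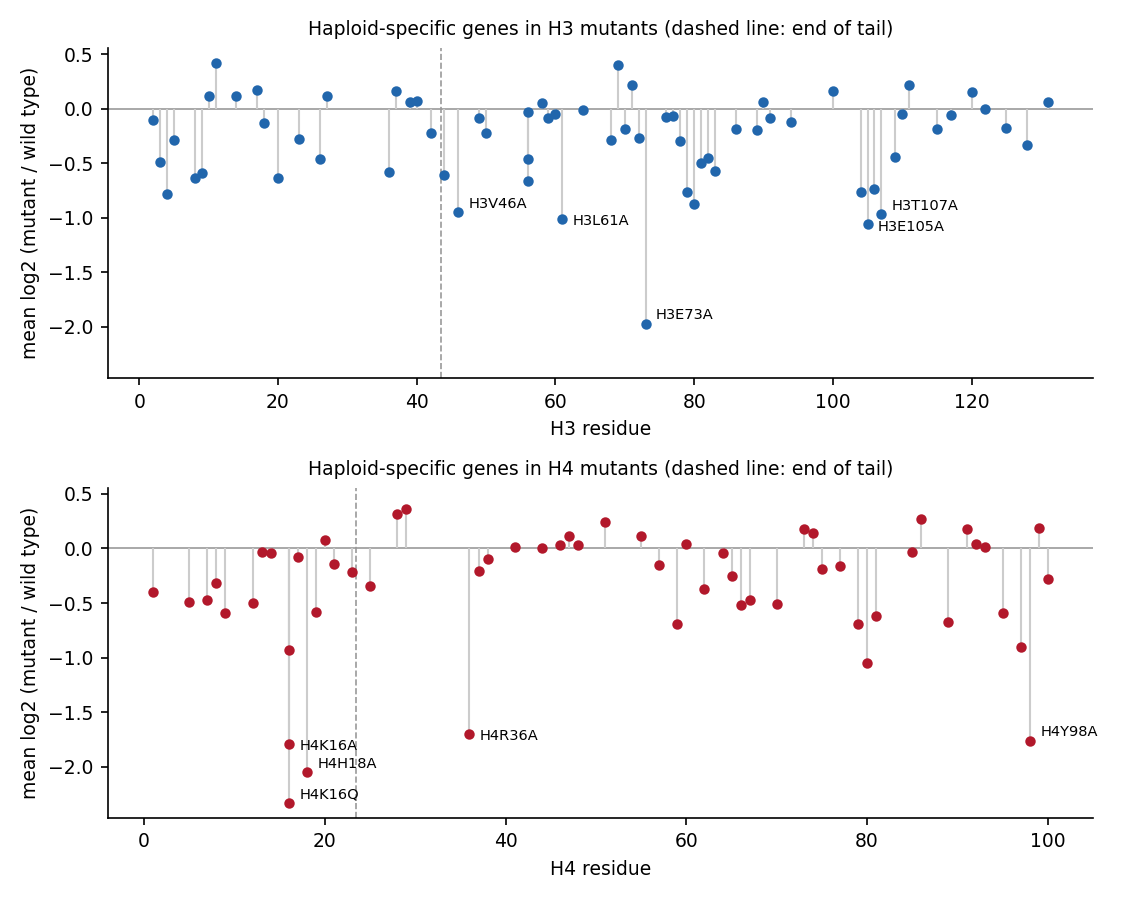
Mean log2 ratio of mutant to wild type over the 13 haploid-specific genes, by residue, for H3 mutants and H4 mutants in separate panels, 1 point per array, with a dashed line at the end of the tail. The lowest means were −2.33 in H4K16Q, −2.05 in H4H18A, −1.97 in H3E73A, −1.79 in H4K16A and −1.76 in H4Y98A.

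The size of each mutant's change was counted as genes at least 2-fold from the mean of the 4 wild types. The largest counts were in H4T80A (2122), H4L97A (2112), H3K36A (2110), H4Y98A (2029) and H3D106A (1991). SFG1, a regulator of filamentous growth, stood 5.51, 5.41, 5.35 and 6.13 above wild type on the log2 scale in the first 4 of these. In H4T80A, the hexose transporter HXT3 was at −9.0, the cyclin PCL1 at 5.35 and RNR1 at 5.33. In H4L97A, the phosphate transporter PHO84 was at 5.46 and the cell wall protein UTR2 at 5.62. In H3K36A, which removes a methylated lysine, COX3 was at 5.23, YOR186W at −5.83 and GID10 at −4.92. In H4Y98A, RNR1 was at 5.60 and SPG1 at −5.52. In H3D106A, the acetate transporter ADY2 was at 9.41, PCK1 of gluconeogenesis at 7.29, RGI2 at 7.67, HXT4 at −6.08 and HXT3 at −5.79. H3K4A, H3K79A and H4K16A, at other modified lysines, had 1011, 748 and 964 genes. In H3K4A, GPD2 was at 4.67, YGR027W-A at 4.17 and YLR264C-A at −5.08, and in H3K79A they were at 4.36, 4.42 and −4.98. In H4K16A, YOL014W was at 5.30, PRY3 at 4.99, GPD2 at 4.55, BAR1 at −4.94, YLR264C-A at −4.81 and STE2 at −4.66. The files give no detection call. The wild-type levels of SFG1 (5.48), ADY2 (5.51), COX3 (5.28) and PCL1 (5.80), HXT3 in H4T80A (5.44) and YLR264C-A in H3K4A, H3K79A and H4K16A (5.40, 5.50 and 5.68) lay near that of HHT2 (5.0), so the sizes of these differences are uncertain.

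The median count was 686 genes per mutant (4 to 2122), and each wild-type array against the mean of the other 3 gave 1 gene. The 8 mutants on the wild-type slide had a median of 56.5 (4 to 302), and those on other slides one of 711 (174 to 2122). Against the other mutants of its own slide a mutant had a median of 80.5 genes (0 to 1584, without H3V117A, alone on its slide), and in the deposited ratios 108 (5 to 1509). On that slide basis H4T80A had 1208 genes, H4L97A 1584, H3K36A 1268, H4Y98A 1345 and H3D106A 564, against 1201 in H3K56A and 1171 in H3Q68A. In the deposited ratios the same 5 had 926, 1509, 885, 841 and 264, and H3Q68A 1300. Also on the slide basis, H3K4A had 83 genes, H3K79A 4 and H4K16A 450, and GPD2 was at 0.11, 0.32 and 2.99 in these mutants. On it HXT3 was at −8.73 in H4T80A, SFG1 at 1.71, 2.71, 3.94 and 2.92 in H4T80A, H4L97A, H3K36A and H4Y98A, PHO84 at 4.19 in H4L97A, ADY2 at 4.88 and PCK1 at 3.58 in H3D106A, and BAR1 at −5.34 and STE2 at −4.69 in H4K16A. RNR1 was at 1.48 in H4T80A and 1.31 in H4Y98A, PCL1 at 2.57 in H4T80A, UTR2 at 3.59 in H4L97A, and COX3 at 1.60, YOR186W at −4.48 and GID10 at −4.01 in H3K36A. SPG1 was at −3.76 in H4Y98A, and RGI2 at 3.25, HXT4 at −2.08 and HXT3 at −2.10 in H3D106A. YGR027W-A was at 0.04 and 0.11 in H3K4A and H3K79A, and YLR264C-A at −0.22, −0.36 and −2.74 in these and H4K16A, where YOL014W was at 1.98 and PRY3 at 2.30.

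**Figure D4:**
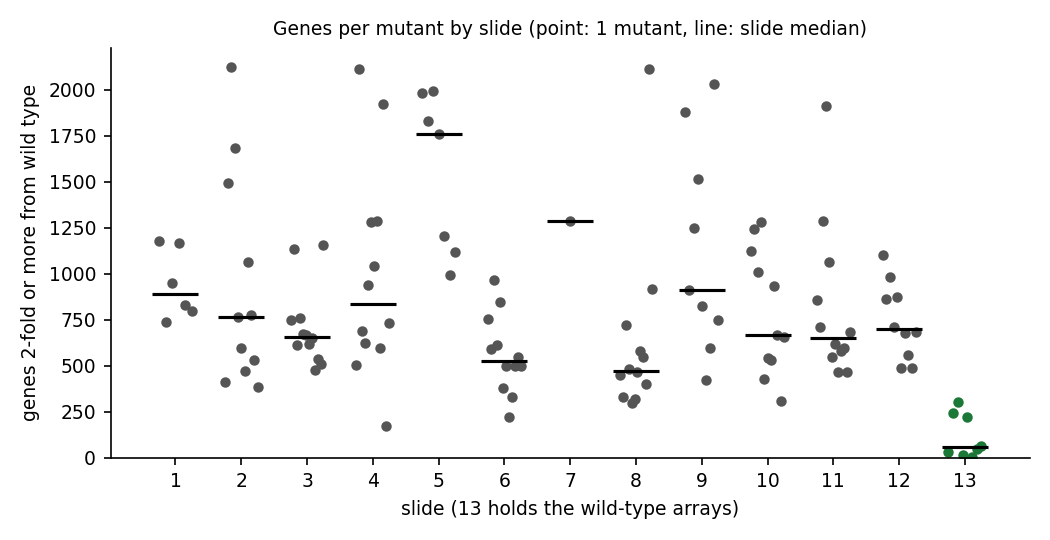
Genes at least 2-fold from the wild-type mean for each of the 123 mutants, by slide, 1 point per array; the line is the slide's median and slide 13, with the wild types, is in green. The median was 56.5 on slide 13 and 711 over the mutants of other slides.

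Profiles of mutants at neighbouring residues were compared over the 1000 most variable genes in the deposited ratios. These ratios share the wild-type arrays of their histone in every pair, including the pairs compared against. H4 mutants 1 or 2 residues apart had a mean r across genes of 0.421 (63 pairs) against 0.271 for other H4 pairs. The difference of 0.150 had one-sided permutation p = 1e-05, the smallest that 100000 permutations give, and 24 such pairs on different slides differed by 0.137 (p = 5e-05). H3 neighbours had a mean r of 0.307 (64 pairs) against 0.207, a difference of 0.10 (one-sided permutation p = 0.00092), but the 16 pairs on different slides differed by 0.02 (p = 0.26). The 64 pairs include H3E105A with H3T107A and H3F104A with H3D106A, nearly identical arrays described below, and no value without them was computed. With positions permuted within slides the difference in slide-centred scanner values was 0.249 for H4 (permutation p = 1e-05) and 0.183 for H3 (permutation p = 2e-05). Most slides held mutants in the order of their residues (on slide 6, positions 1 to 12 held residues 13 to 29). This permutation thus cannot separate neighbouring residues from neighbouring array positions. Genes are not independent replicates in these correlations.

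Substitutions at 1 residue were compared in the same way. The H3K56 profiles of alanine and arginine correlated at r = 0.645 across genes, those of alanine and glutamine at 0.377 and those of arginine and glutamine at 0.293, against a median of 0.221 over all H3 pairs. Their mean of 0.438 was matched or exceeded by 3591 of 45760 trios of H3 mutants, a share of 0.078. The H4K16 profiles correlated at 0.462, 0.544 and 0.434 in that order, against a median of 0.291, and their mean of 0.48 was matched or exceeded by 3098 of 29260 trios of H4 mutants, a share of 0.11. Neither share was under 0.05. In centred scanner values the H4K16 mean was 0.487 with a share of 0.033, where the arginine and glutamine arrays, on the same slide, correlated at 0.866. In the same values the H3K56 mean was 0.096 with a share of 0.40, where alanine correlated at −0.098 with arginine and −0.29 with glutamine, and arginine with glutamine, on the same slide, at 0.677.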

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

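The tests of a shared RNA, of neighbouring residues, of a shared effect of the mutants and of the wild-type slide and the brightness of the arrays in the H4K16 mutants, the slopes for other slides, and all counts of other splits, were chosen after the results were seen. A single array stood apart from its group in 4 of 72 tests, and chance gives about 1 in 20.

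Among the 5 mutants of H4 residues 16 to 20, H4K16A had a mean ratio of −0.29 over the phosphate regulon, against 0.16 to 0.29 in the other 4. Among the 9 mutants of H3 residues 73 to 83, H3E73A stood low for the haploid-specific genes (−1.97, others −0.87 to −0.07) and for the a- and alpha-specific genes (−2.35, others −0.80 to −0.05). In the same group H3T80A stood low for the stress response (−0.79, others −0.42 to −0.06).

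Of the 1213 genes called between all mutants and wild type, the slide of the wild types is a candidate source. If it were, the 8 mutants on that slide should differ from the mutants of other slides as the wild types do, and over the genes called the first difference had a slope of 0.81 on the second, in a test set before the result was seen, where the mutants of 11 other slides in their place gave −0.11 to 0.13. An effect shared by the mutants stays open. The difference on the wild-type slide had a slope of 0.21 on the difference called, which is nearly the complement of 0.81 and shares the 4 wild types. Mutants of weak effect on that slide would give both slopes too. These 8 had 29 to 716 genes each in the deposited ratios, against a median of 108 over all mutants. Against the other mutants of their slide they had 11, 14, 16, 40, 78, 172, 223 and 259, where the median over mutants was 80.5. In the scanner values, against the wild types of their own slide, these 8 had 4 to 302 genes. Each of them had more in the ratios, while the median over all mutants fell from 686 to 108 there. The ratio counts thus do not show that the effects of these 8 are as large as those of other mutants. Whether their effects are weak depends on the measure. Among other splits, 2 of 100 gave as many genes, the real one included (real 1213, highest other 1396 with H4A89S, H4L97A, H3Q5A and H3Q68A, from 4 slides). Since another group of 4 arrays gave more genes, this share under 0.05 means only that such a count is rare among random groupings. The splits ignore the slide, so they do not exclude it.

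The haploid-specific genes were lower in the H4K16 mutants. The slide as a source is argued against by H4K16R and H4K16Q on the wild-type slide itself, where the higher of both means differed by −0.84 from the lowest wild type, against a wild-type range of 0.02. Loss of silencing at HML, which would bring the regulators of both mating types into a cell, stays open. Across all mutants but H3V117A, alone on its slide, HMLALPHA2 and the haploid mean had r = −0.04 (rho −0.027, permutation p = 0.66, adjusted p = 0.66, family of 5). Without the 2 farthest, r was −0.055. The bound set beforehand was wrong, because HMLALPHA2 followed HMRA2 at r = 0.982 over the arrays and read 11.95 in wild type, where HML is silent, so its probes read other copies too. The mean of the silent mating loci was 8.65 in H4K16A, 8.65 in H4K16R and 9.05 in H4K16Q, against 8.68 to 8.85 in wild type. That mean includes HMLALPHA2, so it cannot decide the question either. Low array intensity is argued against for H4K16R and H4K16Q, whose lower median lay 112.3 above the lowest wild type on their slide, beyond the wild-type range of 84.2, and stays open for H4K16A on another slide (r = 0.185 over the mutants, rho 0.204, permutation p = 0.042, adjusted p = 0.07; 0.152 without the 2 farthest).

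On slide 5, H3E105A and H3T107A had profiles with r = 0.969 across genes after slide means were removed (residual SD 0.096), and H3F104A and H3D106A had r = 0.956 (residual SD 0.115), the 2 highest of 585 pairs on a slide. Dim arrays stay open as the source, although r was at least 0.967 in both among the brightest quartile of genes. The pairs matched in median intensity (475.6 with 507.8, and 227.2 with 289.1), while the other arrays of slide 5 read 600.3 to 902.9. A contrast of dim with bright arrays could remain in bright genes after slide means were removed, so that test cannot decide it. Likeness of neighbouring residues is argued against by the adjacent residues of this stretch, with r of 0.459, 0.471 and 0.457 (mean 0.462). A single RNA or culture measured under 2 labels cannot be told apart from mutants that are alike, since the residual SD of 0.115 lies next to the largest of the wild-type pairs, 0.111, and to 0.116 of H4G28A with H4I29A. No other biological explanation was tested.

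Other splits of the same arrays were counted for the remaining comparisons. For H3 against H4 mutants 1 of 100 splits, the real one, gave as many genes (real 1977, highest other 233). For the H4 tail it was 1 of 100 (54, 46) and for H4K16 1 of 35 (10, 0). These shares under 0.05 mean only that such counts are rare among other groupings of the same arrays. For H4K16 1 of 35 is the smallest share possible, and 0 genes passed when any wild-type array was left out. The H4 tail count lay close to that of another split, and 0 genes passed without the lowest quartile of genes by level. All of these splits ignore the slide, and those of H3 and H4 mutants also mix the 2 wild types behind the ratios, so neither is excluded by them. For the H3 tail (100 of 100 splits; real 0, highest other 27), H3K56 (35 of 35; 0, 0), H4 residues 16 to 20 (100 of 100; 0, 585) and H3 residues 73 to 83 (100 of 100; 0, 11), a real count of 0 makes every split as large, so the splits say nothing about chance. The split with 585 genes grouped H4G28A, H4I29A, H4A38S, H4T73A and H4T80A, which points to a structure of the samples whose source was not tested.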

How the results depend on the processing

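The settings with mutants of the wild-type slide only, without the arrays with native histone signal, without the dimmest slide, with single arrays or the H4K16 substitutions left out of haploid-specific means, with list means within slides, and with the other mutants of a slide as reference were chosen after the data were seen. Of the settings for the main results, 96 kept the direction and the side of the threshold, or a count within 1.5 times, 79 moved a count, 1 became weaker and 1 stronger. Of those for single genes and lists 796 kept both, 94 moved, 92 became stronger, 221 weaker and 15 reversed. Unless stated, the cause was not tested. The background alternative was not run, as the files give no background, and dim arrays limit slide 5, where medians started at 227.2.

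No replicate block was possible for mutants, which have 1 array each. Between the wild types, a replicate block gave about 1.2e+02 genes, 54 higher and 63 lower, against 0 by limma without it (224 at an unadjusted p under 0.05). The deviations of same-numbered arrays correlated at 0.596 over 2 pairs, too few to show that the number marks a pairing.

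For all mutants against wild type (1213 genes), limma called 0 genes in the deposited matrix (418 at an unadjusted p under 0.05), 0 with slide as a block (75) and 0 with mutants of the wild-type slide only (519). Separate fits called 73 genes in H3 mutants and 281 in H4 mutants, with fewer samples in each. Leaving out a wild-type array gave 524 to 630. FET3 reversed to −0.02 in the matrix, and to −0.01 with the slide block and on the wild-type slide, where SIT1 reversed to −0.09.

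For H3 against H4 mutants (1977 genes), limma called 0 genes in scanner values with slide as a block (94 at an unadjusted p under 0.05) and 0 in the deposited matrix (70). Ratios with the block gave 174, 166 of them shared, and scanner values without it 2014, of which 803 were shared. Leaving out the lowest quartile of genes by level, with fewer genes tested, gave 1227. NDT80 reversed to −0.13 in scanner values, −0.02 with the slide block and −0.02 in the matrix, RPL15B to −0.01 in the matrix and HMRA1 to −0.11 in scanner values with the block. The mean of the silent mating loci reversed to −0.02 in scanner values within slides.

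For the H3 tail (0 genes by limma, 16 at an unadjusted p under 0.05), scanner values gave 280. For the H4 tail (54), scanner values gave 2068, scanner values with slide as a block 311 and ratios with the block 743. By limma 0 genes were called without the lowest quartile (933 at an unadjusted p under 0.05) and with the tail to residue 29 (414), and 1 without the arrays with native histone signal.

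For H3K56 (0 by limma, 1159 at an unadjusted p under 0.05), the deposited matrix gave 472, slide as a block 331 and the other H3 mutants as control 2. Leaving out 1 array gave 0 to 825, with 347 without H3K56A and 825 without H3K56Q. For H4K16 (10), median-centring gave 3, the dim filter 1, the matrix 476, slide as a block 636, the other H4 mutants as control 41 and H4 wild type alone 0 by limma (284 at an unadjusted p under 0.05). Leaving out 1 array gave 0 to 639, with 0 by limma without any wild-type array (634 to 743 at an unadjusted p under 0.05), 1 without H4K16Q, 136 without H4K16R and 639 without H4K16A. The block and the fit without the alanine array rest on the arrays of slide 13, by construction.

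For H4 residues 16 to 20 (0 by limma, 242 at an unadjusted p under 0.05), scanner values gave 4 and wild type as control 2537. For H3 residues 73 to 83 (0 by limma, 297), wild type as control gave 3645, with FAR1 reversed to 0.27, HO to 0.52, BAR1 to 0.03 and CLN1 to 0.43. Neither group shared a slide with the wild types, so the values with that control also carry the slide.

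With an estimated correlation, camera passed 0 lists in all 8 comparisons that passed lists with the preset one, in the main values, in the deposited matrix and in scanner values with slide as a block. Lists passed with the preset correlation also moved: between wild types from 0 to 6 with median-centring and 8 in the matrix, for all mutants from 5 to 10 in the matrix and 9 with slide as a block, and for H3 against H4 from 7 to 4 in scanner values. For the H3 tail they moved from 13 to 4 in scanner values and 6 in ratios with slide as a block, and for the H4 tail from 8 to 4 in scanner values with it.

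The median of genes per mutant moved from 686 to 108 in the deposited ratios, 80.5 against the other mutants of a slide, 227 with a log2 threshold of 1.5, 1865 with a 1.5-fold threshold and 4091 by limma with each mutant as its own group, where the spread of the wild types alone stands for the lone array. Neighbour similarity in H3 weakened to 0.02 for pairs on different slides (16 pairs), and the H4K16 similarity became stronger, with 0.487 (share 0.033) in centred scanner values, where that of H3K56 moved from 0.438 (share 0.078) to 0.096 (share 0.40).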

Other observations

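The HIS3 test with MFA1 and HIS4 and the test of mitochondrial transcripts without slide 5 were chosen after the result was seen, while the test of these transcripts over all slides was set before.

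Several gene groups stood out in single mutants, which have no replicates. The stress list had its lowest mean ratios in H4L97A (−1.73), H3Q68A (−1.66) and H4T80A (−1.65). H4L97A also had the highest mean of the phosphate regulon (1.04) and of the ribosomal protein genes (0.81), whose lowest mean was −0.70 in H4R92A. The iron regulon ranged from −0.80 in H3S10A to 1.21 in H3L20A. Between all mutants and wild type the histone gene list had a median of −0.24 (camera adjusted p = 0.913) and the retrograde response list one of −0.02 (camera adjusted p = 0.847), and neither list passed in any comparison in the main values.

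Transcripts of the 18 mitochondrially encoded genes were lowest, relative to the slide, in H3K56A (−0.83) and H3H39A (−0.63). Both lay on slide 4, where these transcripts were high, and their levels of 7.23 and 7.43 stood above the 6.52 to 6.66 of the 4 wild types, so they were low only against their slide. A change in respiration with a retrograde response, the nuclear response to mitochondrial dysfunction, would give a clearly negative correlation between these transcripts and the retrograde list. Across all mutants but H3V117A, alone on its slide, r was 0.165 (rho −0.032, permutation p = 0.069, adjusted p = 0.086 in a family of 5; 0.215 without the 2 farthest). That alone would argue against it, but the bound set beforehand took no account of slide 5, the dimmest, without which r was −0.10 (rho −0.128, permutation p = 0.29), within its standard error of 0.094 of that bound. The retrograde list was 0.26 above its slide mean in H3K56A and 0.01 above in H3H39A, so the hypothesis stays open.

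HIS3, a histidine biosynthesis gene, was low in some mutants in which a-specific genes were low. A candidate explanation is that HIS3 in these strains is read from the promoter of the a-specific pheromone gene MFA1, a construct used in yeast genetics. The labels do not give the genotype. Across the same mutants HIS3 and MFA1 had r = 0.94 after slide means were removed (rho 0.865, permutation p = 1e-05, the smallest possible, adjusted p = 5e-05; 0.92 without the 2 farthest). HIS3 and HIS4, a gene of the same pathway, had r = 0.409 (rho 0.278, permutation p = 3e-05, adjusted p = 7.5e-05; 0.384 without the 2 farthest). The hypothesis was found and tested on the same data.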
